A study of Mus musculus with 26 samples.

How the data were processed

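RNA was sequenced from 24 libraries: Hoxa9/Meis1-transformed (H9M) and MN1-transformed mouse myeloid progenitors, control (CTL) or LSD1 knockout (KO), with or without 1 µM ATRA, 3 libraries per group. The protocol text gives 4-hydroxytamoxifen (4-OHT, 0.1 µM for 72 h), which activates the CreERT2 recombinase; whether control cells received it, and which part of the gene the floxed allele deletes, is not given in the sources used here. The strain field names a CreERT2-negative line for every sample, knockouts included. Libraries were stranded total RNA, sequenced as 100-base paired reads. H3K4me2 ChIP-seq was done on lineage-negative bone marrow cells of GFI1-WT and GFI1-KD mice, 1 library each.

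Per the submitters' processing notes, RNA reads were aligned to mm10 with STAR 2.5.3, and ChIP reads were processed with CASAVA 1.8.2, BWA (no version given) and bedtools 2.27.0 on GRCm38. The deposited RNA table holds a count per gene and library as whole numbers; the counting tool, its annotation and the strand counted are not given in the sources used here, so values of antisense, overlapping and paralogous genes are uncertain. The deposited ChIP tables hold 1 aligned read per line with its position, strand and a score, which is the mapping quality; reads were counted and the score was used only as a filter. An input library was not used here.

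The count table has 48795 genes, of which 21762 have no count in any library, and totals of 22402558 to 32674685 counts per library. Gene symbols were attached by Ensembl ID; 48349 IDs matched without their version and 446 did not match. Counts were normalised by TMM and filtered by filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 14663 genes. A single negative binomial model of the 8 groups (16 residual degrees of freedom, common biological coefficient of variation 4%) was fitted by glmQLFit, and 14 comparisons were tested by glmQLFTest: 10 between groups directly, the knockout by ATRA interaction in each model, and the difference between the models in the knockout and the ATRA effect. P-values were adjusted by Benjamini-Hochberg within each comparison, two-sided, and a gene was called at an adjusted p under 0.05. Log2 fold changes come from this fit with their standard error. CPM are counts scaled to the library total alone, given as mean and sample SD.

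A total of 20 gene lists (13 programs and 7 cell types, 303 genes, 249 of them tested) was fixed from textbook knowledge, together with the comparisons, thresholds, rule for named genes and alternatives, before the data were examined. They cover monocyte and macrophage markers, neutrophil maturation genes, primary granule genes, leukaemic stem and progenitor genes, retinoic acid response genes, PU.1 targets, GFI1 and GFI1B targets, LSD1 complex members, interferon response, cell cycle, p53 targets and CDK inhibitors, MHC class II and dendritic cell genes, ribosome biogenesis, and erythroid, megakaryocyte, mast cell and basophil, eosinophil, B cell, T and NK cell, and stromal markers. Each list with at least 5 tested members was compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, a prior count of 2 and Benjamini-Hochberg adjustment over the lists; the same test was run with a correlation estimated from the data. Camera compares a list with the other genes, so a list can pass with few called members. Some genes belong to more than 1 list. The list of LSD1 complex members holds Kdm1a, the gene knocked out, which falls by design in the knockout comparisons.

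A gene with no count in a group is given as at least a fold against 3 counts over the group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Genes named in the text follow a rule: Kdm1a, Hoxa9, Meis1, Mn1, Gfi1, Gfi1b and Spi1; the called genes with the largest and the smallest log2 fold change among those with a mean of at least 5 CPM in the higher group and no overlap between the replicates of the groups (chance gives 10% of genes no overlap at 3 against 3), without clone names; and the members of each list with the smallest adjusted p. Interactions and differences used the same rule without the overlap criterion. Fewer genes are named than the rule allows, taken from its top, and some genes named in 1 comparison are given again in another. Cyp26a1 is also shown for every group in the opening check.

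For H3K4me2, reads with a mapping quality of at least 10 were kept, 1 per position and strand, which left 8949072 of 9000433 reads in GFI1-WT and 9538627 of 9588899 in GFI1-KD. No kept read shared its position and strand with another, so the alternative that keeps duplicates uses the same reads. The reference gene table gives no strand, so a promoter was taken as 1 kb either side of the annotated gene end with more reads over both libraries, not the 5' end as planned. Reads scaled to the library total (RPM) with a pseudocount of 1 gave a log2 ratio for 13903 genes. List medians were set against 10000 random lists matched on reads in 20 bins, with 95% intervals of the median from order statistics; ratios of single genes carry 95% exact binomial counting intervals. Named genes needed 100 reads over both libraries. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

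Alternatives were RLE normalization, no filter on low counts, the replicate number as a block, a fit on the 12 libraries of each model, DESeq2 1.42.0, a stricter call (2-fold or more), each library left out in turn, the estimated correlation, and, chosen after seeing the data, H9M knockout counts less the share of control counts that Kdm1a would need if all its counts came from control cells (7.51% with ATRA, 0.69% without); for ChIP, duplicates kept, median-ratio scaling, reads of every mapping quality, windows of 10 kb or 500 bases, and reads over the whole gene, the last also chosen after seeing the data. The workflow was tested on simulated data: in a simulated H9M knockout comparison it recovered 38 of 48 genes set at a log2 change of -1, 33 of 49 at -0.5, 41 of 50 at 0.5 and 40 of 48 at 1, and called 3 unchanged genes; in a comparison with no change it called 0. The simulation changed 200 genes, as many up as down, with counts drawn independently for each gene. It therefore does not check normalization or false calls where a large share of genes changes, as in the knockout comparisons. Reads were not realigned, splicing and intergenic reads were not analysed here, and no peaks were called.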

Results

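The RNA-seq libraries come from myeloid progenitors of C57BL/6 mice transformed by Hoxa9 and Meis1 together (H9M) or by MN1, each as control or LSD1 knockout (KO) cells, with or without 1 µM all-trans retinoic acid (ATRA). Each of the 8 groups has 3 libraries. H3K4me2, a histone mark of active and primed promoters, was measured by ChIP-seq in 1 GFI1-WT and 1 GFI1-KD library of lineage-negative bone marrow. The title of the latter reads GFI-KD, and it is called GFI1-KD here. The labels do not say how the GFI1-KD mice were made. The labels do not say whether replicate libraries are separate cultures, so the p-values below measure only the spread between these libraries. They also do not say whether control cells received 4-hydroxytamoxifen (4-OHT), so every knockout change below, p53 targets included, is not separated from an effect of 4-OHT or of Cre activation. All H9M libraries share 1 sequencing run tag and all MN1 libraries another, so a difference in level between the models and a difference between runs cannot be told apart.

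Kdm1a, the gene of the histone demethylase LSD1 (ENSMUSG00000036940.15, GRCm38 chromosome 4, 136550533 to 136602787), was examined first, library by library. In H9M controls it had 138, 140 and 139 CPM (counts scaled to the library total) without ATRA and 147, 145 and 150 CPM with ATRA. In H9M knockout cells without ATRA it had 0.937, 0.998 and 0.952 CPM. With ATRA the H9M knockout libraries had 11.5, 10.3 and 11.5 CPM, from 259, 261 and 318 counts. MN1 controls had 187, 193 and 192 CPM without ATRA and 203, 192 and 196 CPM with ATRA. MN1 knockout libraries had 1.41, 1.28 and 1.58 CPM without ATRA and 2.22, 1.85 and 2.36 CPM with ATRA. Every knockout library therefore lay below every control library of its model.

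The genes that name the models, and a target of ATRA, were examined next. Hoxa9, a homeobox transcription factor (ENSMUSG00000038227.15, chromosome 6, 52223097 to 52227370), had 27467 ± 440 CPM in H9M controls without ATRA and 79.9 ± 4.58 CPM in MN1 controls without ATRA (mean ± SD, n = 3). Its partner Meis1 (ENSMUSG00000020160.18, chromosome 11, 18880428 to 19019651) had 229 ± 7.05 CPM in the same H9M controls and no counts in the same MN1 controls, and 3, 2 and 0 counts in MN1 controls with ATRA. The coactivator gene Mn1 (ENSMUSG00000070576.4, chromosome 5, 111417300 to 111457030) had 59.3 ± 4.30 CPM in MN1 controls without ATRA and no counts in any H9M library. Counts of Hoxa9, Meis1 and Mn1 do not tell a transforming copy from the cells' own gene, here and in the lists below. Cyp26a1, which encodes the enzyme that breaks down retinoic acid, had no counts in either control group without ATRA. With ATRA it reached 14.6 ± 1.93 CPM in H9M controls and 1.84 ± 0.601 CPM in MN1 controls.

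**Figure D1:**
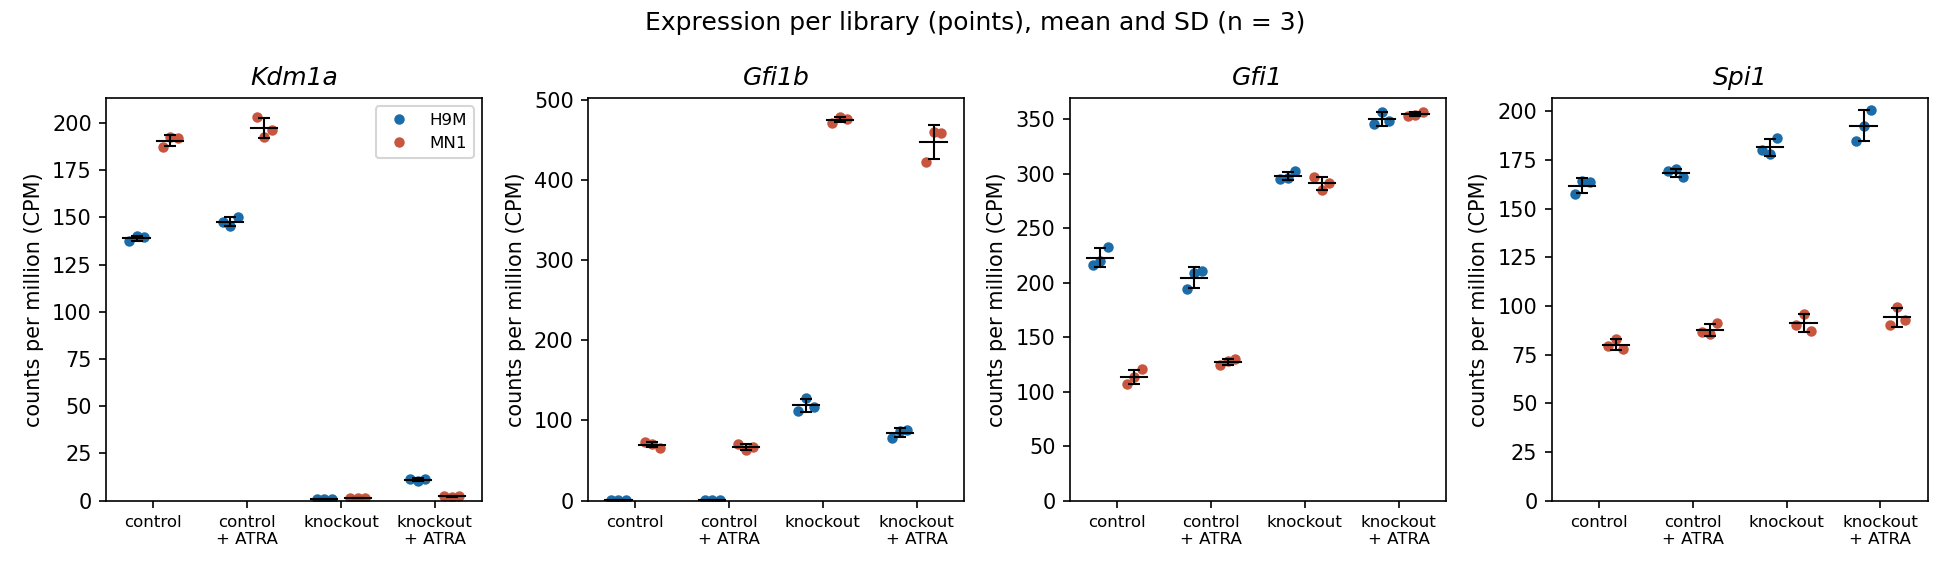
Expression of Kdm1a, Gfi1b, Gfi1 and Spi1 per library, with CPM on a linear y axis from 0 and the 4 groups of each model on the x axis; points are libraries, black bars the mean and SD (n = 3), H9M in blue and MN1 in red. Gfi1b stands at 119 CPM in H9M and 475 CPM in MN1 knockout cells, against 0.138 and 69.8 CPM in controls.

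In H9M cells without ATRA, the LSD1 knockout raised and lowered many genes. Kdm1a fell by 7.15 ± 0.07 on the log2 scale (SE), 142-fold lower. Mmp8, the neutrophil collagenase (ENSMUSG00000005800.2, chromosome 9, 7558429 to 7568486), rose 913-fold, from 1.71 ± 0.078 to 1548 ± 144 CPM (log2 fold change 9.83 ± 0.09, adjusted p = 7.02e-35). Gfi1b, whose product is a zinc-finger repressor that recruits LSD1 (ENSMUSG00000026815.14, chromosome 2, 28609450 to 28621982), rose 839-fold, from 0.138 ± 0.021 to 119 ± 8.12 CPM. Slc15a3, a lysosomal peptide transporter, rose from 0.075 ± 0.038 to 54.6 ± 0.916 CPM. The membrane protein gene Ptgfrn rose at least 142-fold, from no counts to 5.36 ± 0.711 CPM. Tarm1, a receptor of granulocytes and macrophages, had 3 control counts over the group, which puts its ratio at 194 to 2760. Among the falls, the crosslinking enzyme gene Tgm2 (ENSMUSG00000037820.15, chromosome 2, 158116405 to 158146392) went from 117 ± 2.08 to 1.03 ± 0.319 CPM (log2 fold change -6.79 ± 0.09). Bpifc, a lipid-binding protein gene, went from 38.0 ± 0.629 to 2.10 ± 0.614 CPM. Thbs1, which encodes the matrix protein thrombospondin 1, went from 1414 ± 17.2 to 102 ± 5.58 CPM. Gfi1, the paralog of Gfi1b (ENSMUSG00000029275.17, chromosome 5, 107716655 to 107725805), rose 1.35-fold, from 223 ± 8.94 to 298 ± 3.90 CPM. Spi1, the gene of PU.1 (ENSMUSG00000002111.8, chromosome 2, 91082374 to 91115759), rose 1.13-fold, from 162 ± 3.73 to 181 ± 4.36 CPM.

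The gene lists moved by program in this comparison. All 18 tested monocyte and macrophage markers rose (18 adjusted over the list alone), with a median log2 fold change of 2.10 and a camera adjusted p of 8.48e-13. Mpeg1, a pore-forming protein of macrophages, rose 12.1-fold to 201 ± 5.04 CPM, and Csf1r, the receptor for M-CSF, rose 38.6-fold to 46.3 ± 1.28 CPM. Of 24 PU.1 target genes, 17 rose and 1 fell (17 and 1 adjusted over the list alone, median 0.76, adjusted p = 1.6e-07). Irf8, a transcription factor of monocytes and dendritic cells, rose 49.4-fold to 395 ± 5.46 CPM, and Cybb, the catalytic subunit of the phagocyte oxidase, rose 84.2-fold to 246 ± 2.45 CPM. Of 15 neutrophil maturation genes, 11 rose and none fell (11 and 1 adjusted over the list alone, median 1.33, adjusted p = 1.34e-05); Anxa1, an annexin of granulocytes, rose 12.2-fold. Of 17 GFI1 and GFI1B target genes, 11 rose and 2 fell (11 and 3 adjusted over the list alone, median 0.43, adjusted p = 0.0002). The p53 targets and CDK inhibitors had 10 higher and 1 lower of 16 (median 0.41, adjusted p = 0.000718), among them Cdkn1a, the gene of p21, which rose 5.29-fold to 117 ± 5.40 CPM.

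Interferon response genes also leaned upwards in the H9M knockout, with 13 higher and 2 lower of 19 (median 0.50, adjusted p = 0.00646), as did retinoic acid response genes, with 6 higher and 1 lower of 16 (median 0.75, adjusted p = 0.0328). Oasl2, an interferon-induced OAS-like gene, rose from 0.213 ± 0.056 to 4.73 ± 0.477 CPM, and the surface enzyme gene Cd38 rose 46.9-fold to 27.0 ± 1.46 CPM. Of 5 eosinophil markers, 3 rose (median 1.99, adjusted p = 0.0473, and adjusted p = 0.0762 with an estimated correlation). These 4 lists, p53 targets included, had the same counts adjusted over the list alone. Ribosome biogenesis genes fell, 17 of 18 (17 adjusted over the list alone), with a median of -0.31 and an adjusted p of 2.84e-08. The nucleolar chaperone gene Npm1 fell 1.30-fold, from 1696 ± 48.8 to 1287 ± 27.2 CPM. Of 20 cell cycle genes, 14 fell and none rose (14 and 1 adjusted over the list alone, median -0.17, adjusted p = 0.000718, and adjusted p = 0.0954 with an estimated correlation). The replicative helicase subunit gene Mcm7 fell from 393 ± 6.15 to 301 ± 2.13 CPM.

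The other lists did not pass in the H9M knockout. Stem and progenitor genes split into 7 higher and 7 lower of 22 (median 0.00, adjusted p = 0.818). Cd34, a surface marker of progenitors, rose 4.55-fold to 964 ± 18.6 CPM, while Kit, the stem cell factor receptor, fell from 268 ± 4.33 to 133 ± 2.60 CPM. Primary granule genes had 5 higher and 2 lower of 10 (5 and 4 adjusted over the list alone, adjusted p = 0.369), with the myeloperoxidase gene Mpo higher by 1.51-fold at 8253 ± 127 CPM. MHC class II and dendritic cell genes had 7 higher and 2 lower of 13 (8 and 2 adjusted over the list alone, median 2.20, or 0.84 with genes of 3 or fewer counts at their bound, adjusted p = 0.0549). LSD1 complex members had 2 higher and 8 lower of 16, with a negative median, a positive mean and a test pointing down (-0.11, 0.30, adjusted p = 0.138). This list holds both Kdm1a, the gene knocked out, and Gfi1b (log2 fold change 9.71). Megakaryocyte markers (4 of 9 higher, adjusted p = 0.0549), stromal markers (5 higher and 1 lower of 7, adjusted p = 0.0549), mast cell and basophil markers (3 higher and 1 lower of 10, adjusted p = 0.336), erythroid markers (2 of 5 higher, adjusted p = 0.539) and B cell markers (1 higher and 2 lower of 6, adjusted p = 0.539) did not pass either. T and NK cell markers had 4 tested members, too few for camera, of which 3 were called higher.

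edgeR's quasi-likelihood test called 7557 of 14663 genes in this comparison, 51.5%, with 3834 higher and 3723 lower. At 2-fold or more the counts were 1273 higher and 241 lower. Among the 20 lists, 10 of the 19 that camera could test were called, 8 up and 2 down, and 8 with an estimated correlation.

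**Figure D2:**
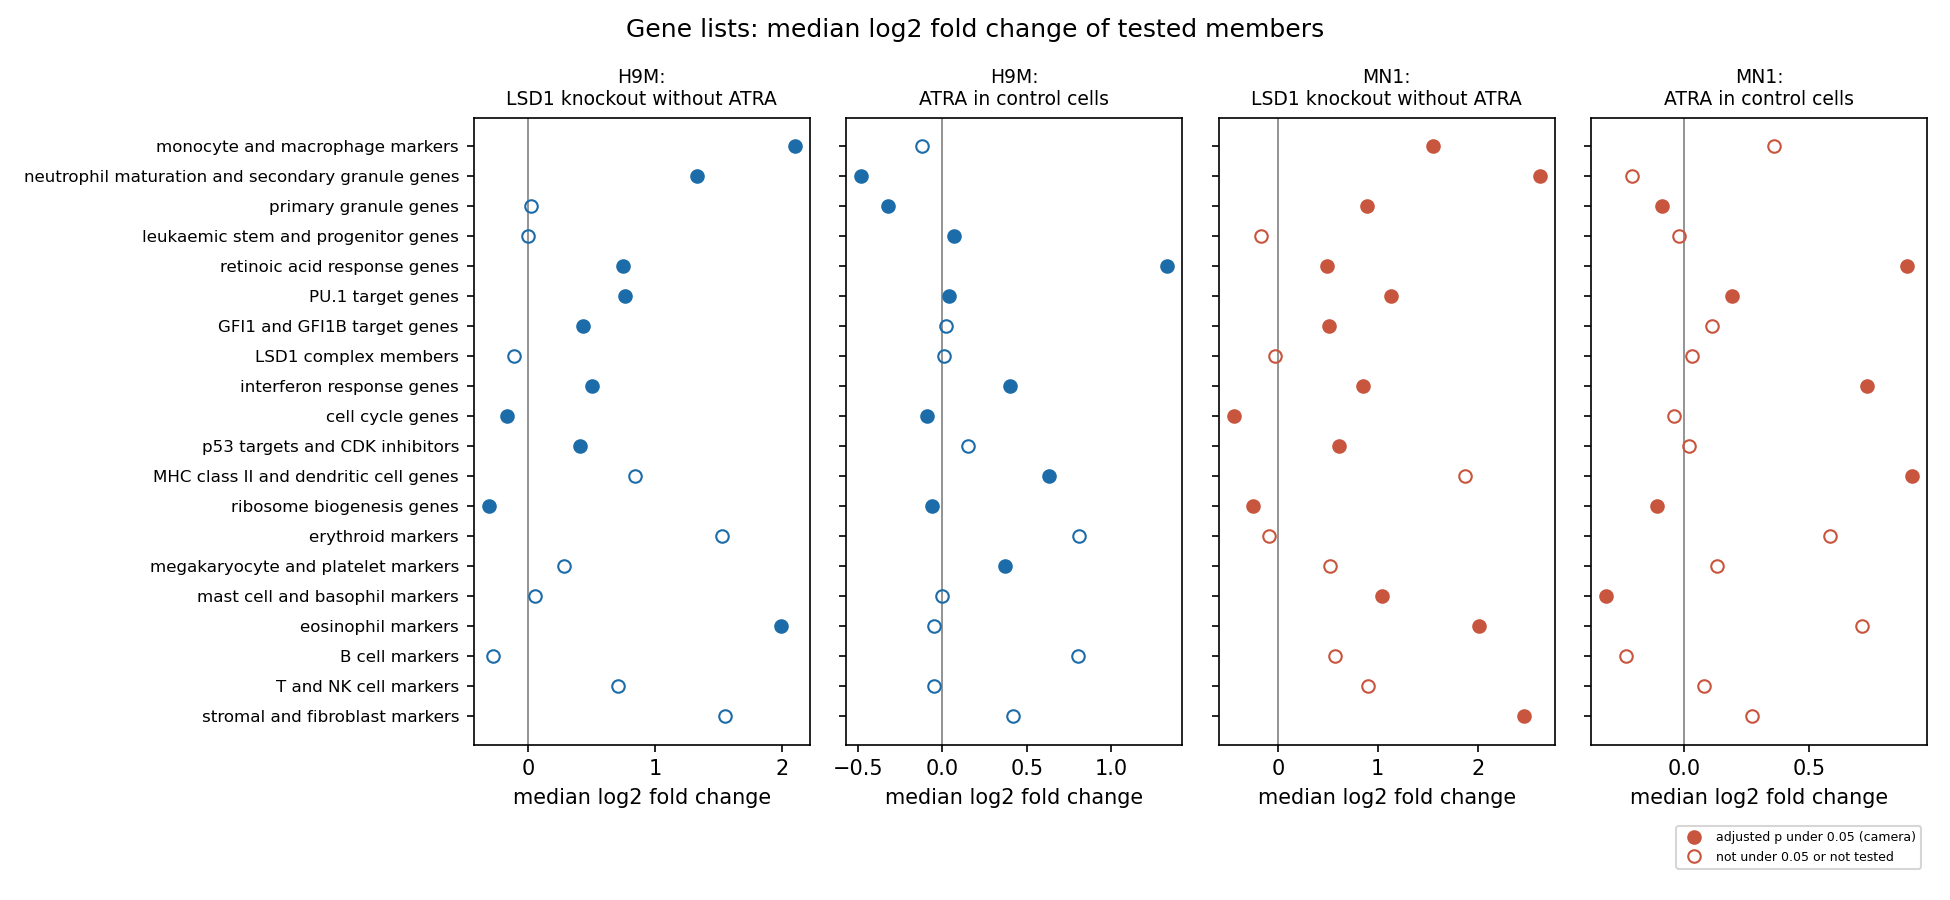
Median log2 fold change (x axis) of the tested members of each list (y axis) in the knockout and the ATRA comparison of each model, with genes of 3 or fewer counts at their bound, filled where camera's adjusted p with the preset correlation is under 0.05, and with x axes that differ between panels. Monocyte markers stand at 2.10 in the H9M knockout and 1.55 in the MN1 knockout, and ribosome biogenesis genes at -0.31 and -0.25.

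ATRA in H9M control cells raised retinoic acid response genes and lowered granule genes. Cyp26a1 (ENSMUSG00000024987.5, chromosome 19, 37697738 to 37701536) rose at least 387-fold. Cyp26b1, another retinoic acid hydroxylase gene, had 2 counts over the untreated group, which puts its ratio at 88.6 to 2660. Hic1, a zinc-finger repressor gene and retinoid target, rose from 0.062 ± 0.055 to 16.7 ± 0.326 CPM (log2 fold change 7.99 ± 0.43, and 8.63 without control replicate 2 without ATRA). The non-muscle myosin gene Myh14 rose from 0.42 ± 0.152 to 86.4 ± 5.15 CPM. Sorcs2, a sorting receptor gene, rose 152-fold, from 1.95 ± 0.383 to 291 ± 8.09 CPM (log2 fold change 7.25 ± 0.10, adjusted p = 7.08e-30). S100a8, a calcium-binding protein gene of neutrophils, fell from 18.4 ± 0.549 to 1.30 ± 0.274 CPM. Mpo fell from 5516 ± 37.3 to 1446 ± 10.4 CPM (log2 fold change -1.89 ± 0.04, adjusted p = 1.96e-26). Gfi1 and Spi1 did not pass (log2 fold change -0.09 ± 0.04, adjusted p = 0.0995, and 0.10 ± 0.04, adjusted p = 0.0884), though Spi1 passed with RLE normalization (0.11, adjusted p = 0.0473) and DESeq2 (0.109, adjusted p = 0.0374). Hoxa9 rose 1.37-fold and Meis1 1.43-fold, in counts that do not tell a transforming copy from the cells' own gene.

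Of 16 retinoic acid response genes, 10 rose and 2 fell in H9M controls given ATRA (10 and 2 adjusted over the list alone, median 1.33, adjusted p = 1.92e-10). Dhrs3, a retinaldehyde reductase gene, rose 3.57-fold to 85.0 ± 3.59 CPM and Tgm2 rose 2.41-fold to 276 ± 1.57 CPM. Primary granule genes fell, 8 of 10 with 1 higher (8 and 1 adjusted over the list alone, median -0.32, adjusted p = 2.55e-06), and the neutrophil elastase gene Elane went from 2447 ± 39.8 to 1253 ± 11.6 CPM. Neutrophil maturation genes had 9 lower and 3 higher of 15 (9 and 3 adjusted over the list alone, median -0.48, adjusted p = 0.00268), with Mmp9, the gelatinase gene, among the higher at 15.9 ± 1.88 against 0.805 ± 0.022 CPM. These 3 lists also passed with an estimated correlation. Monocyte markers went both ways, with 6 higher and 5 lower of 18 (6 and 6 adjusted over the list alone, median -0.12, adjusted p = 0.979); the coagulation factor gene F13a1 fell 2.73-fold while Adgre1, the macrophage marker F4/80, rose 4.66-fold to 55.5 ± 2.5 CPM.

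A further 7 lists passed with the preset correlation alone. MHC class II genes had 4 higher of 13 (adjusted p = 0.00797, and adjusted p = 0.0628 with an estimated correlation), with the class II chain gene H2-Ab1 at 64.5 against 37.4 CPM. Megakaryocyte markers had 3 higher of 9 (adjusted p = 0.0209, and adjusted p = 0.0628 with an estimated correlation). PU.1 target genes had 9 higher and 3 lower of 24 (10 and 3 adjusted over the list alone, median 0.04, adjusted p = 0.0209, and adjusted p = 0.155 with an estimated correlation). Interferon genes had 6 higher and 2 lower of 19 (7 and 2 adjusted over the list alone, adjusted p = 0.0388, and adjusted p = 0.159 with an estimated correlation). Stem and progenitor genes had 10 higher and 2 lower of 22 (adjusted p = 0.0388, and adjusted p = 0.165 with an estimated correlation). Cell cycle genes had 1 higher and 9 lower of 20 (1 and 11 adjusted over the list alone, adjusted p = 0.00278, and adjusted p = 0.165 with an estimated correlation). Ribosome biogenesis genes had 5 lower of 18 (7 adjusted over the list alone, adjusted p = 0.0117, and adjusted p = 0.204 with an estimated correlation). The GFI1 target list did not pass (3 higher and 4 lower of 17, median 0.02, mean -0.07, test down, adjusted p = 0.551). edgeR called 3695 genes, 25.2% of those tested, with 1887 higher and 1808 lower, and 287 higher and 106 lower at 2-fold or more.

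With ATRA present, the LSD1 knockout in H9M cells again raised the lists of monocyte markers, PU.1 targets and neutrophil maturation genes. Kdm1a fell by 3.73 ± 0.05 on the log2 scale, 13.3-fold lower. Gfi1b rose 980-fold to 84.7 ± 5.39 CPM and Mmp8 rose 544-fold to 523 ± 7.47 CPM. Siglec1, a sialic acid receptor of macrophages, rose at least 390-fold, from no counts to 16 ± 2.23 CPM. Mpo rose from 1446 ± 10.4 to 4927 ± 216 CPM, and Mmp9 from 15.9 ± 1.88 to 268 ± 20.1 CPM. Thbs1 fell from 967 ± 28.4 to 42.1 ± 5.14 CPM and Tgm2 from 276 ± 1.57 to 22.8 ± 1.48 CPM. With 7.51% of the control counts removed from the knockout libraries, the level of Kdm1a, Tgm2 fell to 2.21 CPM; Thbs1 stood at 4.36% of controls, so a share of 7.51% is more than Thbs1 leaves room for and its value after removal has no meaning. Of 18 monocyte markers, 17 rose (17 adjusted over the list alone, median 1.55, adjusted p = 5.61e-10), and of 24 PU.1 target genes, 19 rose and 2 fell (19 and 2 adjusted over the list alone, median 0.57, adjusted p = 4.16e-07). Neutrophil maturation genes had 11 higher of 15 (12 adjusted over the list alone, median 2.47, or 1.27 with low-count genes at their bound, adjusted p = 1.41e-06). GFI1 targets (12 higher and 2 lower of 17, adjusted p = 8.76e-05) and retinoic acid genes (12 higher and 2 lower of 16, adjusted p = 0.00326) rose, with the same counts adjusted over the list alone. Ribosome biogenesis genes fell, 16 of 18 (16 adjusted over the list alone, median -0.36, adjusted p = 1.47e-08).

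Interferon genes (13 higher and 3 lower of 19, adjusted p = 0.0123, and adjusted p = 0.0616 with an estimated correlation), p53 targets (10 higher and 2 lower of 16, adjusted p = 0.00726, and adjusted p = 0.0579 with an estimated correlation) and cell cycle genes (1 higher and 10 lower of 20, adjusted p = 0.04, and adjusted p = 0.31 with an estimated correlation) passed with the preset correlation alone. Adjusted over the list alone these counts were 14 and 3, 10 and 2, and 2 and 10. edgeR called 7493 genes, 3917 higher and 3576 lower, with 1216 higher and 238 lower at 2-fold or more.

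Between H9M knockout libraries without and with ATRA, Kdm1a itself was 11.7-fold higher, at 0.962 ± 0.031 and 11.1 ± 0.654 CPM (log2 fold change 3.54 ± 0.10, adjusted p = 1.6e-22), which does not show whether the knockout cells changed. Sorcs2 rose 959-fold to 231 ± 14.7 CPM, and Hic1 rose from 0.147 to 54.0 ± 4.00 CPM. Tgm2 rose 22.1-fold and Mmp9 136-fold. Kdm1a stood at 7.51% of its level in control cells with ATRA, and with that share of the control counts removed from the knockout libraries with ATRA, Tgm2 went from 1.03 to 2.21 CPM (log2 fold change 1.14, adjusted p = 0.00664); with 0.69% also removed from those without ATRA, it went from 0.227 to 2.21 CPM (3.23, adjusted p = 7.84e-06). S100a9, the partner of S100a8, fell from 5.34 to 0.30 CPM, the secreted glycoprotein gene Olfm1 from 31.3 to 4.11 CPM, F13a1 from 501 to 121 CPM and Mmp8 from 1548 to 523 CPM. Retinoic acid genes had 10 higher and 2 lower of 16 (11 and 3 adjusted over the list alone, median 1.86, or 1.57 with low-count genes at their bound, adjusted p = 3.1e-10). Neutrophil maturation genes had 9 lower and 3 higher of 15 (10 and 3 adjusted over the list alone, median -0.92, adjusted p = 0.0039), and with the control share removed from the libraries with ATRA 8 lower and 3 higher (adjusted p = 0.00745, and adjusted p = 0.0511 with an estimated correlation, or 0.0475 with the share removed from all H9M knockout libraries). Primary granule genes (7 lower and 3 higher of 10, adjusted p = 0.0039, and adjusted p = 0.158 with an estimated correlation), ribosome biogenesis genes (9 lower and 1 higher of 18, adjusted p = 0.00751, and adjusted p = 0.204 with an estimated correlation) and stem genes (10 higher and 5 lower of 22, adjusted p = 0.0395, and adjusted p = 0.204 with an estimated correlation) lost their call with an estimated correlation. Adjusted over the list alone these were 7 and 3, 11 and 2, and 10 and 5. Monocyte markers had 11 lower and 5 higher of 18 and did not pass (median -0.48, adjusted p = 0.0909). edgeR called 4305 genes, 2044 higher and 2261 lower.

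Knockout with ATRA set against untreated H9M controls gave 8249 called genes, 4162 higher and 4087 lower, of which 1470 and 268 at 2-fold or more. Cyp26a1 rose at least 805-fold to 30.3 ± 2.70 CPM, and P2rx7, an ATP-gated channel gene of myeloid cells (ENSMUSG00000029468.17, chromosome 5, 122643927 to 122692336), rose from 0.086 ± 0.052 to 102 ± 1.90 CPM. Thbs1 fell 32.5-fold and Bpifc fell by 3.84 ± 0.12 on the log2 scale. Called up were the lists of monocyte markers (15 higher and 1 lower of 18), PU.1 targets (18 and 2 of 24), GFI1 targets (13 and 2 of 17), retinoic acid genes (12 and 3 of 16), p53 targets (11 and 0 of 16), MHC class II genes (8 and 0 of 13) and neutrophil genes (9 and 4 of 15), with the same counts adjusted over the list alone, and interferon genes (15 and 0 of 19; 16 and 0 adjusted over the list alone). Ribosome biogenesis genes were called down, 16 of 18 (16 adjusted over the list alone, median -0.44, adjusted p = 1.73e-08). Stem genes (14 higher and 3 lower of 22, adjusted p = 0.014) and cell cycle genes (14 lower of 20, adjusted p = 0.000336) each had an adjusted p = 0.0813 with an estimated correlation; their counts were the same adjusted over the list alone.

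The interaction asks whether ATRA acts differently in H9M knockout and control cells. Kdm1a had an interaction of 3.42 ± 0.11 on the log2 scale (adjusted p = 1.14e-19), with 0.962 and 11.1 CPM in knockout libraries without and with ATRA and 139 and 148 CPM in controls. Tgm2 had 3.20 ± 0.13 (adjusted p = 4.66e-17), with 1.03 to 22.8 CPM in knockout cells and 117 to 276 CPM in controls. With 7.51% of the control counts removed from the knockout libraries with ATRA, Tgm2 was not called (-0.13, adjusted p = 0.933), and it was 1.96 (adjusted p = 0.031) with 0.69% also removed from those without ATRA. Sdc1, the gene of syndecan-1, had 3.38 ± 0.29, with 2.78 to 31.7 CPM in knockout cells and 0.894 to 0.955 CPM in controls. P2rx7 had -3.01 ± 0.47, with 6.78 to 102 CPM in knockout cells and 0.086 to 11.1 CPM in controls. Sulf2, a heparan sulfatase gene, had -2.92 ± 0.22, with 7.95 to 23.3 CPM against 0.389 to 8.65 CPM. Monocyte markers were called down (2 higher and 7 lower of 18, the same adjusted over the list alone, median -0.34, adjusted p = 0.00119), as were megakaryocyte markers (2 lower of 9, 4 adjusted over the list alone, adjusted p = 0.00306), and retinoic acid genes were called up (1 higher and 1 lower of 16, 2 and 1 adjusted over the list alone, median 0.24, adjusted p = 0.00119). These 3 lists hold with an estimated correlation, and with the control share also removed from the libraries with ATRA, monocyte markers passed with the preset correlation (adjusted p = 0.0166) but not with an estimated one (adjusted p = 0.125, or 0.11 with the share removed from all H9M knockout libraries). PU.1 targets (adjusted p = 0.00828, and adjusted p = 0.108 with an estimated correlation), cell cycle genes (adjusted p = 0.00828, and adjusted p = 0.232 with an estimated correlation), primary granule genes (adjusted p = 0.0304, and adjusted p = 0.231 with an estimated correlation) and MHC class II genes (adjusted p = 0.0463, and adjusted p = 0.207 with an estimated correlation) do not. edgeR called 739 genes, 330 with a positive and 409 with a negative interaction.

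In MN1 cells without ATRA, the knockout lowered Kdm1a 134-fold. Stab1, a scavenger receptor gene of macrophages (ENSMUSG00000042286.13, chromosome 14, 31139017 to 31168651), rose 446-fold, from 1.08 ± 0.21 to 480 ± 25.1 CPM (log2 fold change 8.80 ± 0.09, adjusted p = 6.52e-34). Ptgfrn rose at least 156-fold, from no counts to 5.31 ± 0.498 CPM. Siglec1, with 2 control counts over the group, had a ratio of 204 to 6110, and Ltbp2, a matrix protein gene with 1 control count, a ratio of 108 to 23900. Slc15a3 rose from 0.355 to 78.8 CPM. Tgm2 fell from 67.5 ± 2.00 to 3.43 ± 0.275 CPM (log2 fold change -4.30 ± 0.07, adjusted p = 3e-28), the sphingomyelinase gene Smpd3 from 15.2 to 1.16 CPM and the cadherin gene Cdh23 by 2.54 ± 0.16 on the log2 scale. Gfi1 rose 2.56-fold, from 113 ± 6.75 to 291 ± 6.13 CPM, and Gfi1b 6.78-fold, from 69.8 ± 3.61 to 475 ± 3.25 CPM. Spi1 rose 1.13-fold, from 80.1 ± 2.71 to 91.1 ± 4.56 CPM (adjusted p = 0.000685).

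Of 24 PU.1 target genes, 20 rose and 1 fell in the MN1 knockout (20 and 1 adjusted over the list alone, median 1.13, adjusted p = 2.86e-09), among them Clec5a, a C-type lectin receptor of myeloid cells, from 1.76 to 28.2 CPM. Neutrophil maturation genes had 12 higher of 15 (12 adjusted over the list alone, median 2.62, adjusted p = 1.35e-07), with Mmp8 35.4-fold higher at 438 ± 20 CPM. Monocyte markers had 14 higher and 1 lower of 18 (14 and 1 adjusted over the list alone, median 1.55, adjusted p = 1.83e-05), with the Ly6C gene Ly6c2 33.4-fold higher at 70.9 ± 0.822 CPM. Primary granule genes had 8 higher of 10 (8 adjusted over the list alone, median 0.89, adjusted p = 1.15e-05); Ms4a3, a granulocyte-monocyte progenitor gene, rose from 53.5 ± 5.91 to 287 ± 8.60 CPM and Mpo from 1071 ± 26.1 to 2251 ± 48.4 CPM. Mast cell and basophil markers had 9 higher of 10 (9 adjusted over the list alone, median 1.04, adjusted p = 3.07e-05), with the histidine decarboxylase gene Hdc 3.27-fold higher at 1465 ± 27.7 CPM. All 20 cell cycle genes fell (20 adjusted over the list alone, median -0.44, adjusted p = 1.79e-11), Mcm2, another helicase subunit gene, from 430 to 296 CPM. Ribosome biogenesis genes fell, 16 of 18 (16 adjusted over the list alone, median -0.25, adjusted p = 4.31e-06).

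In the same comparison p53 targets (12 higher and 1 lower of 16, adjusted p = 3.07e-05), interferon genes (13 and 1 of 19, adjusted p = 0.000637), GFI1 targets (11 and 3 of 17, adjusted p = 0.000887), eosinophil markers (4 and 0 of 5, adjusted p = 0.00935), stromal markers (4 and 1 of 7, adjusted p = 0.0166) and retinoic acid genes (10 and 1 of 16; 11 and 1 adjusted over the list alone, adjusted p = 0.0315) were called up. Zmat3, a p53-induced RNA-binding protein gene, rose from 47.4 ± 2.91 to 173 ± 6.27 CPM. All 13 called lists hold with an estimated correlation, and except for retinoic acid genes the counts were the same adjusted over the list alone. Not called were MHC class II genes (8 higher and 2 lower of 13, median 1.87, adjusted p = 0.0505), megakaryocyte markers (7 and 2 of 9, adjusted p = 0.166), stem genes (5 and 12 of 22, median -0.17, adjusted p = 0.247), LSD1 complex members (5 and 6 of 16, adjusted p = 0.581), B cell markers (0 and 1 of 6, median 0.57, mean -0.15, test down, adjusted p = 0.758) and erythroid markers (2 and 0 of 5, median -0.09, mean 0.21, test up, adjusted p = 0.823). Of the 4 T and NK cell markers tested, 2 rose and 2 fell. edgeR called 8071 genes, 55% of those tested, 4212 higher and 3859 lower, with 1449 higher and 210 lower at 2-fold or more.

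ATRA in MN1 control cells raised Sorcs2 439-fold, from 0.096 ± 0.094 to 42.6 ± 4.15 CPM (log2 fold change 8.78 ± 0.19, adjusted p = 3.38e-24). It was 9.62 without control replicate 1 without ATRA and 8.17 without control replicate 2 without ATRA. Eln, the elastin gene, had 1 count over the untreated group, which puts its ratio at 103 to 22700. P2rx7 rose from 0.926 ± 0.177 to 25.2 ± 4.78 CPM. Ms4a3 fell from 53.5 ± 5.91 to 12.6 ± 1.73 CPM (log2 fold change -2.12 ± 0.08, adjusted p = 5.49e-19), the basophil protease gene Mcpt8 from 8.13 ± 0.083 to 1.91 ± 0.065 CPM and the granzyme B gene Gzmb from 7.00 ± 0.149 to 1.65 ± 0.467 CPM. Kdm1a, Gfi1b and Spi1 did not pass (adjusted p = 0.637, 0.263 and 0.0789). Retinoic acid genes had 11 higher and 1 lower of 16 (11 and 2 adjusted over the list alone, median 0.89, adjusted p = 6.9e-07), with Tgm2 2.70-fold higher at 185 ± 2.51 CPM. PU.1 targets had 10 higher and 2 lower of 24 (12 and 2 adjusted over the list alone, median 0.19, adjusted p = 0.000863), with Irf8 2.63-fold higher at 24 ± 1.78 CPM. MHC class II genes (5 higher of 13, the same adjusted over the list alone, adjusted p = 0.000978) and interferon genes (6 higher of 19, 8 adjusted over the list alone, adjusted p = 0.00293) were also called up. Mast cell and basophil markers were called down (1 higher and 6 lower of 10, 2 and 7 adjusted over the list alone, median -0.31, adjusted p = 0.000978).

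These 5 lists hold with an estimated correlation. Ribosome biogenesis genes (9 lower of 18, 16 adjusted over the list alone, adjusted p = 8.16e-05, and adjusted p = 0.0591 with an estimated correlation) and primary granule genes (3 higher and 5 lower of 10, the same adjusted over the list alone, adjusted p = 0.0247, and adjusted p = 0.202 with an estimated correlation) do not. Neutrophil maturation genes did not pass (2 higher and 4 lower of 15, adjusted p = 0.277), nor did monocyte markers (8 and 3 of 18, adjusted p = 0.0781). edgeR called 3199 genes, 1669 higher and 1530 lower, with 277 higher and 63 lower at 2-fold or more.

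With ATRA present, the knockout in MN1 cells lowered Kdm1a 92.5-fold and raised Gfi1 2.74-fold and Gfi1b 6.59-fold, while Spi1 did not pass (log2 fold change 0.08, adjusted p = 0.108) but did with RLE normalization (0.113, adjusted p = 0.0249), DESeq2 (0.112, adjusted p = 0.0268) and without knockout replicate 1 with ATRA (0.112, adjusted p = 0.0381). Siglec1 rose at least 465-fold, from no counts to 16.2 ± 0.76 CPM, and Stab1 from 1.36 to 382 ± 28.3 CPM. The matrix protein gene Smoc1 fell from 7.20 to 0.495 CPM. Ms4a3 rose from 12.6 to 142 CPM, Mmp8 from 8.35 to 267 CPM and Hdc from 401 to 1410 CPM. Called up were neutrophil genes (12 higher and 0 lower of 15, median 2.42), PU.1 targets (20 and 1 of 24, median 0.77), primary granule genes (8 and 0 of 10), p53 targets (12 and 0 of 16), monocyte markers (11 and 1 of 18, median 1.33), interferon genes (13 and 1 of 19), mast cell markers (8 and 0 of 10), GFI1 targets (9 and 1 of 17), retinoic acid genes (13 and 1 of 16), eosinophil markers (3 and 0 of 5) and stromal markers (4 and 0 of 7). Called down were cell cycle genes (20 of 20, median -0.45, adjusted p = 7.4e-11) and ribosome biogenesis genes (15 lower and 1 higher of 18, adjusted p = 1.13e-05). The counts adjusted over the list alone differed for PU.1 targets (21 and 1), monocyte markers (12 and 1) and interferon genes (13 and 2). All 13 lists hold with an estimated correlation. edgeR called 8389 genes, 4191 higher and 4198 lower.

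ATRA in MN1 knockout cells raised Cyp26a1 at least 222-fold to 8.62 ± 0.742 CPM and Eln at least 199-fold to 7.76 ± 0.516 CPM, each from no counts. Sorcs2 rose 970-fold and Tgm2 12.4-fold, from 3.43 ± 0.275 to 43.7 ± 3.18 CPM. Gzmb fell from 16 to 2.99 CPM and Mcpt8 from 24.2 to 5.71 CPM. Kdm1a had a log2 fold change of 0.56 ± 0.13 (adjusted p = 0.00994), and it did not pass without knockout replicate 2 without ATRA (0.49, adjusted p = 0.068) or without knockout replicate 3 with ATRA (0.47, adjusted p = 0.0927). Retinoic acid genes (10 higher of 16, 12 adjusted over the list alone, median 1.41, adjusted p = 3.26e-12) and interferon genes (9 higher and 1 lower of 19, 12 and 1 adjusted over the list alone, adjusted p = 6.49e-05) were called up. Mast cell and basophil markers (6 lower of 10, 8 adjusted over the list alone, median -0.53, adjusted p = 1.45e-06) and ribosome biogenesis genes (12 lower of 18, 15 adjusted over the list alone, adjusted p = 4.8e-06) were called down. Primary granule genes had 7 lower and 1 higher of 10 (7 and 3 adjusted over the list alone, adjusted p = 0.000549, and adjusted p = 0.0576 with an estimated correlation). edgeR called 2759 genes, 1234 higher and 1525 lower, so 44.7% were higher; with RLE normalization 55% were.

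Knockout with ATRA set against untreated MN1 controls gave 8889 called genes, 4520 higher and 4369 lower, of which 1705 and 204 at 2-fold or more. Cyp26a1 rose at least 253-fold and Ptgfrn at least 166-fold. Smpd3 fell 30.1-fold, and Homer2, a synaptic scaffold gene, fell from 22.5 to 2.55 CPM. Of 24 PU.1 targets 22 rose (23 adjusted over the list alone, median 1.11, adjusted p = 1.66e-09), and 19 of 20 cell cycle genes fell (19 adjusted over the list alone, median -0.50, adjusted p = 9.62e-11). Monocyte markers (15 and 1 of 18), neutrophil genes (12 and 0 of 15; 12 and 1 adjusted over the list alone), retinoic acid genes (14 and 1 of 16), interferon genes (16 and 0 of 19), GFI1 targets (13 and 1 of 17), p53 targets (11 and 0 of 16), MHC class II genes (9 and 1 of 13) and eosinophil markers (4 and 0 of 5) were called up, and ribosome biogenesis genes down (16 of 18), with the same counts adjusted over the list alone except for neutrophil genes. Primary granule genes (8 and 2 of 10, adjusted p = 0.00481) and stromal markers (4 and 1 of 7, adjusted p = 0.0473) each had an adjusted p = 0.0676 with an estimated correlation.

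For the interaction in MN1 cells, Tgm2 had 2.20 ± 0.10 on the log2 scale (adjusted p = 1.12e-15), with ATRA taking it from 3.43 to 43.7 CPM in knockout cells and from 67.5 to 185 CPM in controls. Clu, the clusterin gene, had 1.5 ± 0.12, with 14.4 to 84.5 CPM against 6.18 to 12.7 CPM. P2rx7 had -1.80 ± 0.20, with 13.9 to 109 CPM against 0.926 to 25.2 CPM, and Cmah, a sialic acid hydroxylase gene, -2.07 ± 0.34, with 3.81 to 5.34 CPM against 0.285 to 1.67 CPM. Retinoic acid genes (2 higher of 16, 3 adjusted over the list alone, median 0.30, adjusted p = 7.92e-05) and stem genes (3 higher of 22, 9 higher and 2 lower adjusted over the list alone, median 0.14, adjusted p = 0.000316) were called up and hold with an estimated correlation. PU.1 targets were called down (1 higher and 3 lower of 24, the same adjusted over the list alone, adjusted p = 0.0156, and adjusted p = 0.121 with an estimated correlation). edgeR called 407 genes, 160 with a positive and 247 with a negative interaction.

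Between the models, knockout effects without ATRA correlated across the 14663 tested genes with a Spearman coefficient of 0.521 and a Pearson coefficient of 0.54; genes are not independent replicates. In both models 5370 genes were called, of which 2486 were higher in both (1101.3 under independence), 2353 lower in both (979.8) and 531 opposite. At 2-fold or more, 700 were higher in both (125.8 under independence), 53 lower in both (3.5) and 30 opposite. ATRA effects in control cells had a Spearman coefficient of 0.249 and a Pearson coefficient of 0.298, with 683 genes higher in both (214.8 under independence), 425 lower in both (188.7) and 202 opposite. Without the filter on low counts the Spearman coefficients were 0.284 for the knockout and 0.118 for ATRA.

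**Figure D3:**
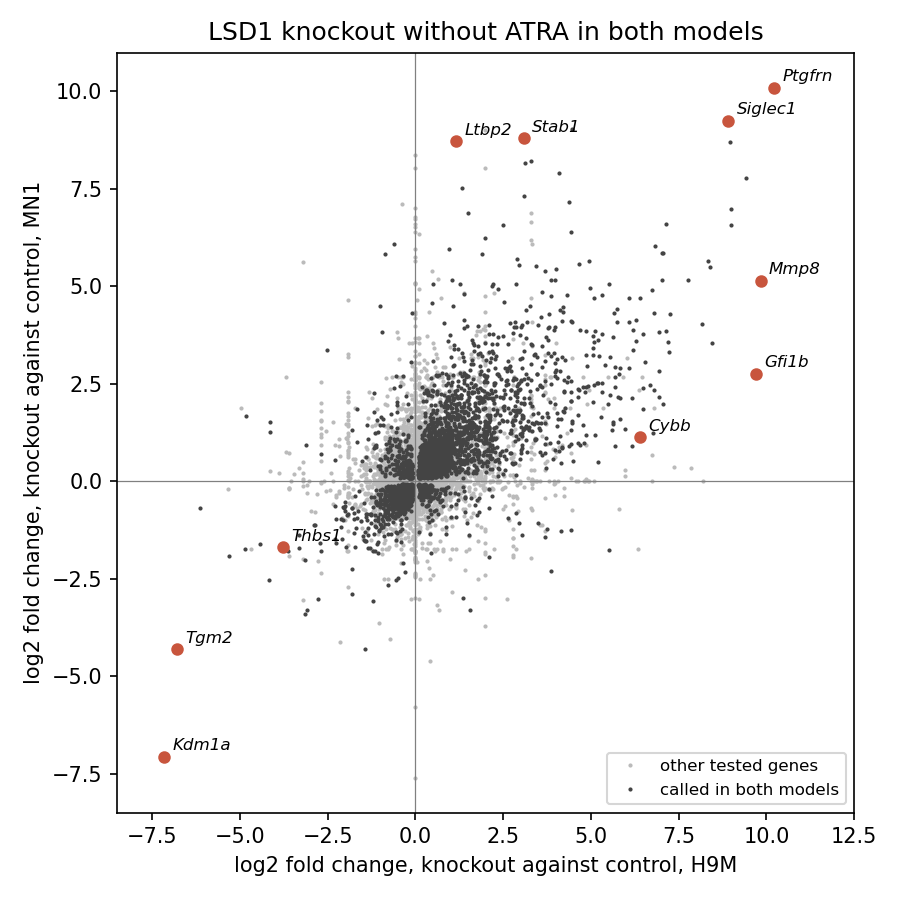
Log2 fold change of each tested gene after the knockout without ATRA in H9M (x axis) and in MN1 (y axis), with the 5370 genes called in both models in black, the others in grey and named genes in red; fitted values of genes with few counts in a group, such as Ptgfrn, Siglec1 and Ltbp2, depend on the prior count. Kdm1a stands at -7.15 in H9M and -7.06 in MN1.

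The difference between the models was tested directly, as the MN1 effect minus the H9M effect. For the knockout, Gfi1b had -6.95 ± 0.19 on the log2 scale (adjusted p = 1.35e-22), with 69.8 to 475 CPM in MN1 and 0.138 to 119 CPM in H9M. Stab1 had 5.72 ± 0.27, with 1.08 to 480 CPM in MN1 and 1.29 to 10.9 CPM in H9M. Smad6, an inhibitor of BMP signalling, had 6.69 ± 0.40, with 0.184 to 10.6 CPM in MN1 and 0.866 to 0.458 CPM in H9M. Cybb had -5.26 ± 0.93, with 0.068 to 0.155 CPM in MN1 and 2.96 to 246 CPM in H9M. Primary granule genes were called up in MN1 relative to H9M (7 of 10, the same adjusted over the list alone, median 0.70, adjusted p = 1.14e-05) and cell cycle genes down (17 of 20, 19 adjusted over the list alone, median -0.30, adjusted p = 6.8e-08), both also with an estimated correlation. Monocyte markers were called down (4 higher and 9 lower of 18, the same adjusted over the list alone, median -0.81, adjusted p = 0.00298, and adjusted p = 0.0525 with an estimated correlation). PU.1 targets did not pass (12 higher and 8 lower of 24, median 0.36, mean -0.39, test up, adjusted p = 0.583). edgeR called 4159 genes, 2080 positive and 2079 negative.

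For ATRA in control cells, Rarb, a retinoic acid receptor gene, had a difference of -6.43 ± 0.56 (adjusted p = 5.57e-10), with 0.321 to 0.293 CPM in MN1 and 0.137 to 10.8 CPM in H9M. Nrip1, a nuclear receptor corepressor gene, had -5.53 ± 0.36 (-6.17 without H9M control replicate 2 without ATRA), with 16.9 to 21.1 CPM in MN1 and 0.061 to 3.71 CPM in H9M. Retinoic acid genes were called down (1 higher and 5 lower of 16, 3 and 5 adjusted over the list alone, median -0.12, adjusted p = 0.00261), as were mast cell and basophil markers (2 lower of 10, the same adjusted over the list alone, adjusted p = 0.00121), both also with an estimated correlation. Stem genes (1 higher and 7 lower of 22, median -0.12, mean 0.06, test down, adjusted p = 0.00261, and adjusted p = 0.0737 with an estimated correlation) and neutrophil genes (4 higher of 15, 4 and 1 adjusted over the list alone, adjusted p = 0.0455, and adjusted p = 0.0903 with an estimated correlation) lost their call with an estimated correlation. edgeR called 2022 genes, 974 positive and 1048 negative.

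H3K4me2 reads at promoters were compared between the GFI1-KD and the GFI1-WT library, with no replicate and so no test between groups. Windows held 25.9% of reads in GFI1-WT (95% exact binomial interval 25.8 to 25.9%) and 26.1% in GFI1-KD (26.0 to 26.1%). The PU.1 target list (24 genes) had a median log2 ratio of 0.772 (95% interval 0.534 to 0.919), with 22 genes higher, against -0.132 to 0.227 for the central 95% of random lists matched on reads. Irf8 had 151 reads in GFI1-WT and 318 in GFI1-KD (ratio 1.98, 1.62 to 2.41), the integrin gene Itgam 59 and 187 (ratio 2.97, 2.21 to 4.06) and Csf1r 59 and 133 (ratio 2.11, 1.55 to 2.92). Spi1 itself had 166 and 363 reads (ratio 2.05, 1.70 to 2.48) and Gfi1 272 and 404 (ratio 1.39, 1.19 to 1.63). Inside Gfi1, windows of 1 kb from 107719001 and 107722001 had 11 and 38 reads in GFI1-WT and none in GFI1-KD, while those from 107717001 and 107718001 had 11 and 14 against 90 and 107, so reads differ unevenly along the gene and its promoter ratio is given with that limit. The GFI1 and GFI1B target list (17 genes) had a median of 0.302 (0.107 to 0.696), with 15 genes higher, against -0.153 to 0.119 for random lists.

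Promoters of genes at least 2-fold higher after the knockout had a median H3K4me2 log2 ratio of 0.287 in H9M (1225 genes, 95% interval 0.25 to 0.35) and 0.273 in MN1 (1393 genes, 0.241 to 0.313). Those of all genes called higher had 0.024 in H9M and 0.042 in MN1, and those called lower -0.06 and -0.072. These 4 medians moved to 0.083, 0.076, -0.108 and -0.119 in windows of 10 kb either side, and to 0.06, 0.077, -0.024 and -0.036 with median-ratio scaling; the median over all 13903 genes was -0.033. Genes at least 2-fold lower had 0.03 in H9M (224 genes, -0.023 to 0.127; -0.025 in windows of 10 kb either side) and 0.064 in MN1 (199 genes, -0.009 to 0.151), against -0.069 to 0.018 and -0.063 to 0.04 for random lists, so in these windows both medians also lay above their random lists, with intervals that overlap them. Random lists for genes at least 2-fold higher had -0.03 to 0.003 and -0.027 to 0.005. Among called knockout genes, the largest ratios were at Ms4a6d, a membrane protein gene of monocytes (chromosome 19, 11586606 to 11604804; 14 and 124 reads, ratio 8.31, 4.77 to 15.6), and Selp, the P-selectin gene (chromosome 1, 164115264 to 164150026; 17 and 138 reads, ratio 7.62, 4.59 to 13.5). The smallest were at the clathrin light chain gene Clta (chromosome 4, 44003816 to 44032846; 126 and 12 reads, ratio 0.0894, 0.045 to 0.162) and Acp5, an acid phosphatase gene (122 and 13 reads, ratio 0.1). Intervals of medians here cover the spread between genes, and those of single genes cover counting error only. Neither covers the spread between animals. Another makeup of the lineage-negative cells, raised below for PU.1 targets, was not separated from the medians of the knockout genes either.

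**Figure D4:**
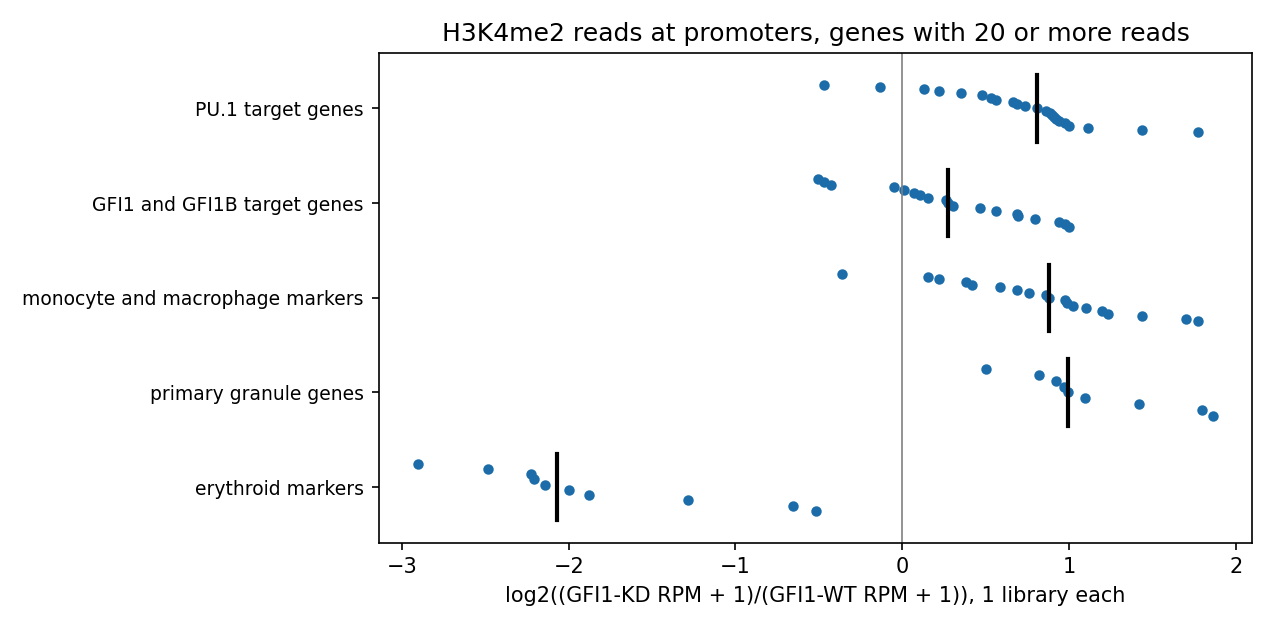
Log2 ratio of H3K4me2 reads at promoters, GFI1-KD over GFI1-WT (x axis, 1 library each, no error bars), for members of 5 lists with at least 20 reads; points are genes and black lines medians. PU.1 targets, without Cybb (1 and 8 reads), have a median of 0.806. Erythroid markers, members not tested in RNA included, have a median of -2.07.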

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

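The comparisons in this part were planned, while the splits of the samples, the removal of control counts, the tests of explanations and the look at chromosome Y were chosen after the results were seen.

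The knockout by ATRA interaction was called in 739 genes in H9M cells and in 407 in MN1 cells. The H9M knockout libraries with ATRA could hold control or unrecombined cells (see Kdm1a below). With 7.51% of the control counts removed from them, 853 genes were called, 677 of them among the 739 and in the same direction, so such cells are argued against as the whole source, but not for Kdm1a. Tgm2 (3.20) had -0.13 after this and 1.96 with 0.69% also removed from the knockout libraries without ATRA, and stays open. Thbs1, at 4.36% of controls, leaves room for less than 7.51%. In H9M the largest interactions were those of Col14a1 (6.77 on the log2 scale) and Kdm1a (3.42), and the smallest those of Barx2 (-3.36) and P2rx7 (-3.01). Col14a1, a collagen gene, had 0.03 to 23.8 CPM with ATRA in knockout cells and 0.039 to 0.285 CPM in controls. It was not called without control replicate 1 (5.91) or control replicate 3 (6.75) without ATRA, or without knockout replicate 3 without ATRA (6.19), and it was 9.58 without knockout replicate 1 without ATRA. Barx2, a homeobox gene, had 8.36 to 3.13 CPM in knockout cells and 0.026 to 0.105 CPM in controls. Its call was lost when 9 of the 12 libraries were each left out, with values of -2.66 (control replicate 1 with ATRA) to -3.73 (control replicate 3 without ATRA). In MN1 the largest were H19 (2.65) and Tgm2 (2.20), and the smallest Cmah (-2.07) and P2rx7 (-1.80). H19, an imprinted noncoding RNA gene, was not called without control replicate 3 without ATRA (2.18). Fitted values of genes with a group of few or no counts, such as Col14a1 and Barx2, depend on the prior count.

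The knockout effect differed between MN1 and H9M in 4159 genes, the largest differences being those of Ltbp2 (7.56) and Smad6 (6.69) and the smallest those of Gfi1b (-6.95) and Apba1 (-6.50). Ltbp2 had 0.011 to 6.86 CPM in MN1 and 0.866 to 1.93 CPM in H9M, and it was 9.29 without MN1 control replicate 3. Apba1, an adaptor protein gene, had 0.047 to 0.027 CPM in MN1 and 0.128 to 7.12 CPM in H9M, and it was -9.17 without MN1 knockout replicate 2 and -7.62 without H9M control replicate 3. The ATRA effect in control cells differed in 2022 genes, from Eln (13.31) and Fbxo2 (5.43) to Cyp26b1 (-6.97) and Rarb (-6.43). Eln had 0.011 to 6.42 CPM in MN1 and 0.113 to 0 CPM in H9M, and it was 15.03 without MN1 control replicate 2 without ATRA. Fbxo2, a ubiquitin ligase subunit gene, had 4.01 to 5.60 CPM in MN1 and 0.141 to 0 CPM in H9M. It was not called without H9M control replicate 1 without ATRA (3.66) or with ATRA (5.43). Cyp26b1 had 1.12 to 2.53 CPM in MN1 and 0.026 to 8 CPM in H9M. Fitted values of Ltbp2, Apba1, Eln, Fbxo2 and Cyp26b1, each with a group of few or no counts, also depend on the prior count. Their size and order are given with that limit. The models were sequenced under separate run tags, but each effect was taken within 1 tag. A run difference that scales a gene alike in all groups cancels out of these differences. A run difference that acts unlike on the groups cannot be told apart from them.

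Splits of the 6 libraries of each direct comparison into other groups of 3 number 10, too few for a share under 0.05. Each split was fitted on the libraries of its comparison alone, so counts differ from those of the full fit. In H9M the real splits called 7307 genes for the knockout, 3056 for ATRA, 6632 for the knockout with ATRA, 3920 for ATRA in knockout cells and 7699 for both together. In MN1 the same comparisons called 8096, 3308, 8230, 2735 and 8536. In each, 1 of the 10 splits, the real one, gave as many, and the highest other called 0. Every other split mixes both groups, so the effect itself enters the spread between libraries. The 0 therefore does not show what chance gives. For the interactions and differences, 100 splits of 12 libraries were drawn. For the H9M interaction 2 of them gave at least the 619 genes of the real one, the other reaching 2831, and for MN1 2 gave at least 405, the other reaching 2847. A split with several times the real count points to a structure of the samples, and regrouping puts the knockout, ATRA and model effects into the spread between libraries, so these splits do not show what chance gives for an interaction or a difference. For the difference in the knockout effect 2 gave at least 4306, the other reaching 4508, and for the ATRA effect 1 gave at least 1869, the highest other reaching 14.

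Kdm1a in H9M knockout cells with ATRA stood at 11.1 CPM, 7.51% of control cells with ATRA, against 0.962 CPM without ATRA. Reads from MN1 libraries are argued against: 15 of 2040 genes with at least 100 CPM in all MN1 libraries lay under the share they would need, 5.09%. Cpa3, a mast cell protease gene, had at least 775.1 CPM in MN1 and at most 0.133 CPM in these 3 libraries. Cells or reads of the H9M control cultures, unrecombined cells included, stay open, since only 1 of 8366 genes with at least 10 CPM in both control groups lay under the lowest share of 6.88% (Thbs1, 42.1 against 967 CPM, 4.36%). A transcript of the recombined locus that ATRA raises also may play a part; Kdm1a had 0.56 in MN1 knockout cells against 3.54 in H9M, which cannot decide, as recombination can differ between the models.

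After the knockout, many more genes were at least 2-fold higher than at least 2-fold lower, 1273 against 241 in H9M and 1449 against 210 in MN1. For both counts to be equal, every gene would have to shift by 0.56 on the log2 scale in H9M and by 0.56 in MN1. RLE moved the median by at most 0.033, so the choice between TMM and RLE is argued against as a source. Both take most genes as unchanged, so a change in total RNA per cell would not show and stays open. Genes near the detection limit are argued against as the whole source, since 80.6% of the H9M genes (228 against 55, 95% binomial interval 75.5 to 85%) and 80.1% of the MN1 genes (214 against 53, 74.9 to 84.8%) with a mean of at least 10 CPM in control cells, which could fall as well as rise, were higher. Direct repression by LSD1, indirect effects of differentiation, and 4-OHT or Cre stay open, as untested.

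Promoters of PU.1 target genes had more H3K4me2 reads in the GFI1-KD than in the GFI1-WT library. A difference in enrichment over all promoters is argued against, since the interval of the list, 0.534 to 0.919, lay above the highest median of the central 95% of matched random lists, 0.227. Another makeup of lineage-negative cells could be a source: erythroid markers had a median of -2.07 (-2.49 to -0.654), with 0 of 10 higher. Magnetic depletion of lineage-positive cells would remove mature erythroid cells, not early progenitors. With 1 library each, an effect of GFI1 on these promoters, another cell makeup and an effect of sex all stay open. The libraries themselves differ in chromosome Y: 4 Y-linked genes had 66 to 76 reads in GFI1-WT and 0 in GFI1-KD. GFI1-WT therefore held cells with a Y chromosome, and GFI1-KD showed none. Chromosome X held 1.91% and 2.058% of reads, which alone does not decide on sex. Whether sex changes these promoters was not tested.

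Chromosome Y was in no comparison. It had 1530 reads in the GFI1-WT library, 171.0 RPM, and 98 in the GFI1-KD library, 10.3 RPM. Kdm5d, Eif2s3y, Uty and Ddx3y, all Y-linked, had 66, 76, 70 and 72 reads in GFI1-WT and 0 each in GFI1-KD, so the 98 reads do not show a Y chromosome there. The labels give no sex for either library.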

How the results depend on the processing

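The whole-gene read count for ChIP and the removal of control counts were chosen after the data were seen, and all other alternative tests were planned. Counts of called genes stayed within 1.5 times under RLE, no filter, a 12-library fit and DESeq2. With the replicate number as a block, counts were close (7554 for the H9M knockout, 8079 for the MN1 knockout, 706 and 389 for the interactions). Residuals of libraries with the same number correlated with a median of 0.012 in H9M and -0.016 in MN1, against -0.024 and 0.006 for different numbers, so the numbers do not pair libraries. RLE shifted the median log2 fold change by at most 0.033. It took genes called higher from 44.7% to 55% for ATRA in MN1 knockout cells (53.4% with DESeq2) and from 39.3% to 48% for the MN1 interaction (49.3%). Among 863 pairs of a named gene and a comparison none reversed in these fits; 859 kept their side of the threshold under RLE, 848 without a filter, 857 with a block and 843 of 861 under DESeq2. The Barx2 interaction in H9M was not called with a block (-3.36, adjusted p = 0.0595). Leaving out a library kept 5231 of 5418 values on their side. Counts near the floor limit folds of rare transcripts. With the control share removed from H9M knockout libraries with ATRA, direction turned for Ebf1 (-0.164) and Kdm1a (-1.779) with ATRA in knockout cells, and for Kdm1a (-1.905) and Tgm2 (-0.129) in the interaction, and with it removed from all H9M knockout libraries for Ebf1 (-0.086). The removal sets the Kdm1a values itself.

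The stricter call (2-fold or more), by its construction, left in H9M 1514 genes for the knockout, 393 for ATRA, 1454 for the knockout with ATRA, 545 for ATRA in knockout cells, 1738 for both together and 93 for the interaction. In MN1 it left 1659, 340, 1719, 289, 1909 and 33, and 908 and 224 for the differences in the knockout and the ATRA effect. Leaving out 1 library gave ranges below each count, since fewer libraries were fitted: in H9M 6990 to 7256, 2987 to 3504, 6864 to 7158, 3515 to 4159, 7678 to 7938 and 576 to 670, and in MN1 7527 to 7620, 2366 to 2817, 7839 to 8008, 2018 to 2411, 8288 to 8414 and 287 to 383. For the differences they were 3726 to 3864 and 1704 to 1964. With an estimated correlation, called lists went to 3 for H9M ATRA, 2 for ATRA in H9M knockout cells, 3 for the H9M interaction and 2 for the difference in the ATRA effect. Without a filter the Spearman coefficients between models were 0.284 (knockout) and 0.118 (ATRA). The cause was not tested.

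H3K4me2 medians moved with the window and scaling, and the cause was not tested. Keeping duplicates could not move them, since no kept read shared its position and strand with another. With 10 kb windows, genes called higher had 0.083 in H9M and 0.076 in MN1, genes called lower -0.108 and -0.119, and genes at least 2-fold lower in H9M -0.025 in place of 0.03. With 500-base windows, genes called lower had -0.077 and -0.103, and genes called higher in MN1 0.028. With median-ratio scaling, genes called higher had 0.06 and 0.077, and lower -0.024 and -0.036. Over the whole gene, genes called higher had 0.079 and 0.066, lower -0.143 and -0.16, and at least 2-fold higher in H9M 0.352. The PU.1 list ran from 0.612 to 0.807 and the GFI1 list from 0.299 to 0.36; Spi1 had 0.64 over the whole gene.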

Other observations

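These values were looked at after the results above were seen and carry no test between groups. H3K4me2 at the promoters of all listed genes with at least 20 reads, tested in RNA or not, differed between lists. Primary granule genes had a median log2 ratio (GFI1-KD over GFI1-WT) of 0.991 (95% interval 0.822 to 1.8), with 9 of 9 higher, and monocyte markers 0.88 (0.416 to 1.197), with 18 of 19 higher. Neutrophil maturation genes had 0.584 (-0.421 to 0.98), with 13 of 20 higher, stem and progenitor genes 0.148 with 17 of 23 higher, and interferon genes -0.149 with 8 of 21 higher. Ribosome biogenesis genes had -0.087, with 3 of 18 higher. Markers of other cells were not all lower, as stromal markers had 0.847 (-0.612 to 1.013), with 5 of 7 higher, T and NK cell markers 0.593 (-0.287 to 1.53), with 4 of 6 higher, and megakaryocyte markers -0.269 (-1.764 to 0.81), with 3 of 8 higher.

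Ribosomal protein genes took a mean of 7.58% of counts in H9M controls, 7.91% with ATRA, 6.34% in knockout cells and 6.17% in knockout cells with ATRA. In MN1 the same groups had 7.5, 7.51, 7.14 and 6.89%. The 10 most abundant genes took 7.28 to 8.98% of counts in H9M libraries and 4.66 to 4.99% in MN1 libraries. Mitochondrial genes took 0.42 to 0.95% of counts over all 24 libraries.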
